A study of Rattus norvegicus with 8 samples.

How the data were processed

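Bone within a margin of 1 mm around titanium implants was taken from the femora of male Wistar rats aged 12 to 13 weeks, 10 days after implantation, with adhering muscle removed per the labels. Rats had a normal or a high-fat diet for 8 weeks. RNA (3 ug) was depleted of ribosomal RNA, made into strand-specific libraries by the dUTP method and sequenced as paired reads of 150 bp. Per the submitters' processing notes, bcl2fastq 1.8.4, HISAT2 2.1.0 and StringTie 1.3.3b were used with genome build Rnor_6.0. The role and order of these tools, the gene annotation, the filters, the test and the circRNA caller are not given in the sources used here. The 4 normal and 4 hyperlipidemic libraries were grouped by the labels and the group letters of the deposited tables, and 0 per-sample columns were left unmatched.

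The authors deposited FPKM values, fragments scaled to locus length and library size, for genes, lncRNAs and circRNAs in each library. For circRNAs the unit is named only by the deposited table as FPKM, since its column headers give sample names alone. The deposited tables also hold a fold change of hyperlipidemic over normal computed by the authors by a formula not given in the sources used here. The deposited log2 value is the binary logarithm of that fold change. The deposited p-value and q-value come from a test of the authors that is not given in the sources used here. Counts were not used here, so the depth per library is unknown and its effect on precision cannot be stated. In the gene workbook 3 further sheets, which repeat the values or name the groups, were not used here. Short, provisional and repeated gene names were kept as deposited. For list members with several loci of one name, the most abundant locus was used.

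Values were analysed in R 4.3.3 with limma 3.58.1. Genes with a mean FPKM of at least 0.5, lncRNAs with a mean of at least 0.1 and circRNAs above 0 in at least 4 libraries were kept. FPKM were taken to log2 after adding 1 for genes and 0.1 for lncRNAs and circRNAs, and no further scaling was applied. A linear model with empirical Bayes moderation and a trend in the prior variance compared hyperlipidemic with normal libraries. A change was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are differences of mean log2 values, whereas fold changes between means are ratios of mean FPKM. Gene lists, each with at least 5 measured members, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Library measures were compared by two-sided exact permutation over the 70 assignments of labels.

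Co-expression was measured as the median Pearson's r between residuals after removal of group means, for lncRNAs with genes within 100 kb and for circRNAs with their host genes. For lncRNAs it was compared with 1000 re-pairings to genes on other chromosomes. For circRNAs it was compared with 1000 shuffles of the same host genes, which can return the true host. The named genes were the 10 with the largest change in each direction among those called, without overlap between groups and with a mean FPKM of at least 1. Names starting with LOC, RGD, AABR, AC, RN or NEWGENE were passed over. To these were added the 4 members with the smallest p of each list described, genes fixed in advance, of which Tnfsf11 fell under the filter, and the 5 lncRNAs and circRNAs with the largest change in each direction. Not every gene that the rule names is reported here.

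The methods were tested on simulated data. For each kind a single simulated set held rows shifted by a log2 change of 1 and other rows shifted by 3. With 100 of 13742 genes shifted at each size, 11 were found at 1 and 81 at 3, with 4 calls on unchanged genes in the set. With 100 of 14233 lncRNAs shifted at each size, 0 were found at 1 and 0 at 3. With 50 of 568 circRNAs shifted at each size, 1 was found at 1 and 26 at 3. No call fell on an unchanged lncRNA or circRNA. Among simulated lists the 1 shifted list was found and 0 of the 19 others. The simulated genes varied independently, whereas the estimated correlation in the real lists reached 0.813 (skeletal muscle). The error rate of the list test under such correlation is therefore not shown. Simulated pairs with a shared signal gave a median r of 0.747 (permutation test, p = 0.00498) and pairs without one 0.00336 (p = 0.831). That test used fewer shuffles than the test of the real pairs and was not centred on their mean. The test of the real pairs was therefore not itself simulated.

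Alternatives were another pseudocount, no filter or a stricter filter on low values, median-of-ratios scaling, quantile normalization, the replicate number as a block, no trend in the prior variance, array quality weights and each library left out in turn. Co-expression was also run with windows of 10 kb and 1 Mb (100000 drawn pairs), with Spearman's rho and with group means kept. Added after the data were seen were 3 libraries per group, only genes above 0 in all 8 libraries, only genes with a span of at least 1 kb, quantile normalization for lists, pairs without overlap and the mean per host gene. The direction of a list was compared between settings only where the list passed in at least 1 of them.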

Results

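Total RNA depleted of ribosomal RNA was sequenced from femoral bone of male Wistar rats 10 days after titanium root-form implants had been placed in both femoral shafts. The 8 libraries fall into 2 groups of 4: a normal group, fed a normal diet, and a hyperlipidemic group, fed a high-fat diet for 8 weeks. The deposited values are FPKM for 19120 gene loci, 14625 long non-coding RNAs (lncRNAs) and 774 circular RNAs (circRNAs). No counts were used here, so the depth of each library is unknown and no counting interval is given. The labels do not say whether the libraries come from separate animals, and the p-values measure only the spread between these 8 libraries. Libraries of the hyperlipidemic group resembled one another more closely than those of the normal group. Across genes, Pearson's r of log2 FPKM lay between 0.917 and 0.960 within the hyperlipidemic group, between 0.723 and 0.901 within the normal group, and between 0.667 and 0.921 across groups. Genes are not independent replicates, so these r values carry no test.

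Some properties of whole libraries differed along with the diet. Transcripts of the mitochondrial genome made up 1.01% ± 0.213 (SD, n = 4) of the gene FPKM in the normal group and 2.29% ± 0.454 in the hyperlipidemic group, without overlap (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 libraries can give). Adjusted over the 10 library measures compared, that p was 0.143. The summed FPKM of these transcripts overlapped (7459 ± 2188 and 12441 ± 2125; exact permutation p = 0.0571), and the total gene FPKM was 745813 ± 177742 in the normal and 547822 ± 37062 in the hyperlipidemic group. Loci of up to 1000 bp took 75.6% ± 7.72 of the gene FPKM in the normal group and 64.6% ± 4.43 in the hyperlipidemic group (exact permutation p = 0.0571, adjusted 0.143). Normal replicate 1 stood apart, with 31 genes listed at 0 that were above 10 FPKM in each of the 7 other libraries, among them the platelet factor Pf4 and the fatty acid binding protein Fabp4, which were picked out after the values were seen. A value listed at 0 is therefore not shown to be an absence of the transcript: Mt-cyb of the mitochondrial genome was at 0 in normal replicate 4 and at 917 FPKM or more in each other library, and Ssb, among the genes at 0 in normal replicate 1, at 21.0 FPKM or more.

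**Figure D1:**
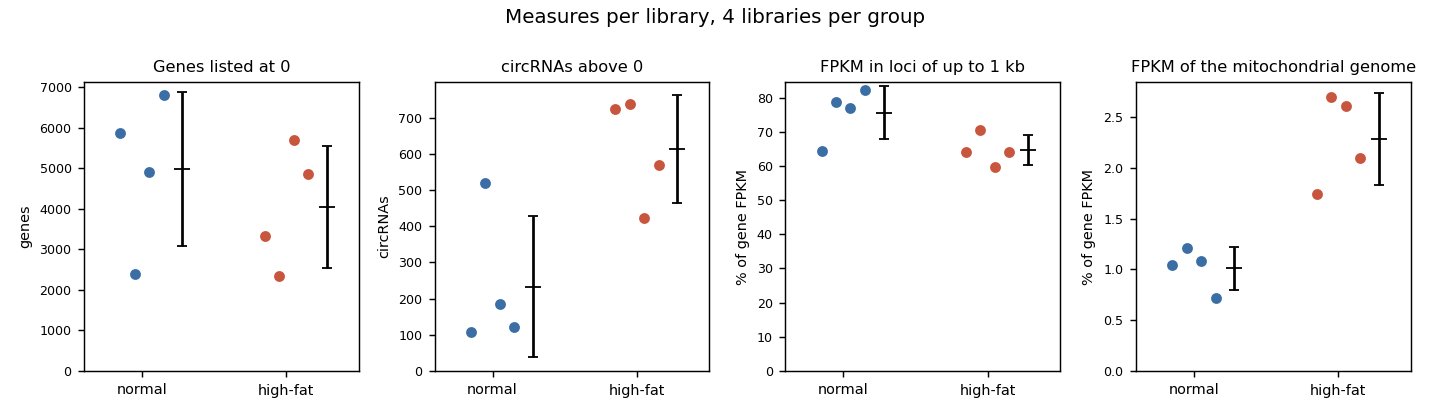
Measures per library: genes listed at 0, circRNAs above 0, and the percent of gene FPKM in loci of up to 1 kb and in the mitochondrial genome. Points are single libraries, 4 per group, and the bars beside them the mean and SD; the mitochondrial share is higher in every hyperlipidemic library (lowest 1.74%) than in every normal one (highest 1.21%).

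The comparison of the groups asks how bone around an implant differs in gene expression between hyperlipidemic and normal rats. The 33 gene lists used below, and the rule for naming genes, were chosen before the data were examined. Of all 13742 genes tested, 65.0% had a log2 change above 0, which is the share to set beside the counts of list members below. Among genes of bone-forming cells, most measured values were lower in the hyperlipidemic group, and 1 gene passed the test over all genes. Bglap, which encodes the bone matrix protein osteocalcin (chromosome 2, 187741770 to 187742747 on Rnor_6.0), fell from 336 ± 64.4 to 140 ± 24.7 FPKM (mean ± SD, n = 4 per group; 2.40-fold between means; log2 change -1.25, limma adjusted p = 0.0201). Its locus spans 978 bp, and 158 of the 171 genes that fell lie at loci of up to 1000 bp. Of the 20 measured members of the osteoblast and bone matrix list, 15 had lower values and 5 higher, with a median log2 change of -0.44. Bglap alone passed over all genes, and 4 members fell when adjusted over the list alone: Bglap, Col1a1, Sparc and Smpd3. Col1a1, the main collagen of bone, measured between 1252 and 1942 FPKM in the normal libraries and between 518 and 1055 in the hyperlipidemic ones (log2 change -1.14, adjusted p over all genes 0.122). Sparc measured 766 ± 239 and 386 ± 93.3 FPKM (-0.97, 0.174). The list as a whole was lower than other genes (limma camera adjusted p = 4.55e-05). This did not hold with an estimated correlation between its genes (adjusted p = 0.176 with an estimated correlation). Other genes of the lineage did not pass over all genes: Runx2 (log2 change -0.29), Sp7 (-0.50), Alpl (-0.10), Spp1 (-0.72), Ibsp (0.07) and Tnfrsf11b (0.24). The sign turned for Ibsp under median-of-ratios scaling (-0.10) and for Tnfrsf11b under quantile normalization (-0.060). On leaving out each library the log2 change ran from -0.56 to 0.22 for Runx2, -0.59 to 0.23 for Alpl and -0.53 to 0.45 for Ibsp. The Bglap call ended without normal replicate 4 or hyperlipidemic replicate 1, 2 or 4 (adjusted p from 0.0684 to 0.0935), while its log2 change stayed between -1.36 and -1.15.

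Among genes of bone-resorbing cells and of bone-embedded osteocytes 1 gene fell, and both lists passed as lower by camera but not with an estimated correlation. Ctsk, the collagen-degrading protease of osteoclasts (chromosome 2, 196655469 to 196666446), fell from 277 ± 97.0 to 87.6 ± 42.2 FPKM (3.17-fold between means; log2 change -1.69, adjusted p = 0.0441). Of 17 osteoclast members 10 were lower and 7 higher. Of these, 1 passed over all genes and 2, Ctsk and Atp6v0d2, when adjusted over the list alone (median -0.31, camera adjusted p = 0.00324; adjusted p = 0.515 with an estimated correlation). Acp5 was at 51.6 ± 20.6 and 30.3 ± 13.4 FPKM (log2 change -0.73, adjusted p = 0.423). Of 11 osteocyte members 8 were lower and 3 higher, among these Sost (log2 change 1.32, with a value of 0 in normal replicate 1). None passed over all genes and 1, Mepe, when adjusted over the list alone, at 77.1 ± 22.9 and 38.3 ± 5.78 FPKM (list median -0.45, camera adjusted p = 0.0156; adjusted p = 0.584 with an estimated correlation). The extracellular matrix list, made of collagens, proteoglycans and remodelling enzymes of repair tissue, had 14 of 18 members lower, none past the threshold over all genes and 1, Tnc, when adjusted over the list alone (35.1 ± 5.25 and 18.1 ± 4.60 FPKM; list median -0.47, camera adjusted p = 0.00540; adjusted p = 0.584 with an estimated correlation). Among the 4 higher members of the matrix list, Aspn was at 0.444 ± 0.629 and 4.37 ± 4.08 FPKM (log2 change 1.68). Ctsk no longer passed without any one library other than hyperlipidemic replicate 2 (adjusted p from 0.0536 to 0.178). The osteocyte list no longer passed without normal replicate 3 (adjusted p = 0.155, median -0.24), nor the matrix list under quantile normalization (0.0513). With 3 libraries per group, replicate 1 of each left out, the osteoclast (0.107), osteocyte (0.0527) and matrix (0.120) lists no longer passed. The osteoclast median was -0.16 without normal replicate 4. The matrix median was -0.27 without normal replicate 1 or hyperlipidemic replicate 3, -0.29 without hyperlipidemic replicate 4 and -0.82 without hyperlipidemic replicate 2. The Wnt pathway list (16 members, 8 lower, median -0.04, camera adjusted p = 0.111) and the BMP and TGF-beta pathway list (23 members, 12 lower, median -0.02 but mean 0.02, camera direction down, adjusted p = 0.205) had no member past the threshold over all genes or adjusted over the list alone. Both lists passed as lower among genes of at least 1 kb (0.0182 and 0.0475), and their medians ran from -0.13 to 0.032 and from -0.047 to 0.15 on leaving out each library.

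**Figure D2:**
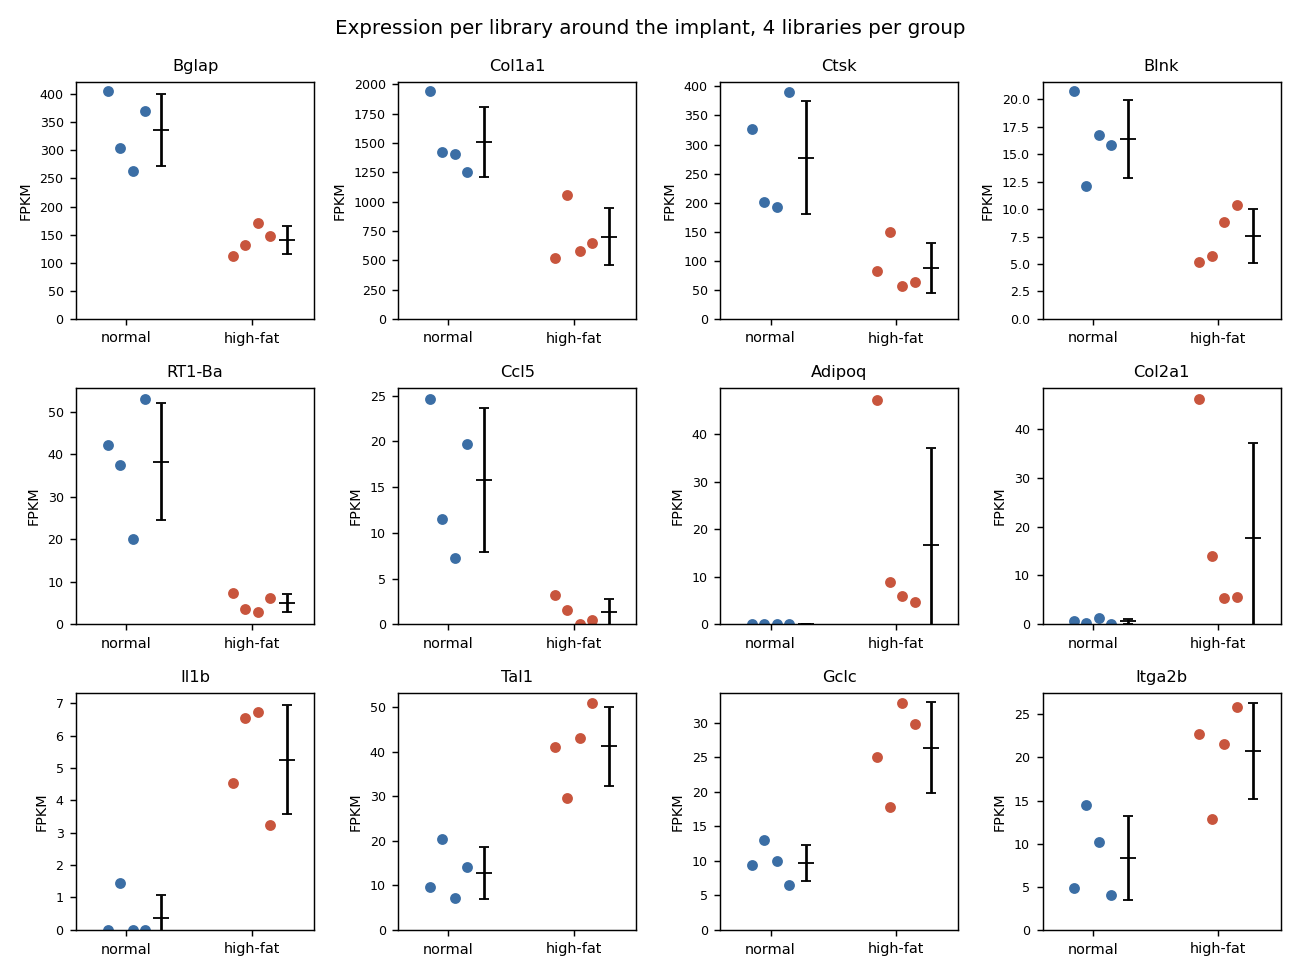
FPKM of 12 genes in each library, with the 4 normal libraries in blue, the 4 hyperlipidemic libraries (labelled high-fat) in red, and the mean and SD beside them (bars end at the axis where the SD reaches below 0). Bglap, Col1a1, Ctsk, Blnk, RT1-Ba and Ccl5 lie lower in all hyperlipidemic libraries, and the hyperlipidemic libraries of Adipoq, Col2a1, Il1b, Tal1 and Gclc all lie higher than the normal ones; Itga2b overlaps.

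A few transcripts of fat cells and of cartilage rose from values at or near 0 in the normal group, while other members of their lists were measured in both groups. Adipoq, the fat cell hormone adiponectin (chromosome 11, 81330293 to 81344488), was listed at 0 in normal replicates 1, 3 and 4 and at 0.0994 FPKM in normal replicate 2, against 47.2, 8.81, 5.91 and 4.79 FPKM in hyperlipidemic replicates 1 to 4 (limma adjusted p = 0.0141). Thrsp, a regulator of lipid synthesis in fat and liver, was listed at 0 in normal replicates 1, 3 and 4 and at 0.0172 in normal replicate 2, against 13.8, 4.07, 4.42 and 4.47 FPKM (adjusted p = 0.00435). Col2a1, the collagen of cartilage, was at 0.755, 0.309, 1.32 and 0 FPKM in normal replicates 1 to 4 and at 46.0, 14.0, 5.41 and 5.59 FPKM in hyperlipidemic replicates 1 to 4 (adjusted p = 0.0323). Of 13 adipocyte members 10 were higher. Of these, 1 passed over all genes and 4 when adjusted over the list alone: Adipoq, Plin1, Cidec and Lpl (median 0.53, camera adjusted p = 0.0691). Lpl, which releases fatty acids from lipoproteins, was at 8.71, 9.44, 12.0 and 7.502 FPKM in normal replicates 1 to 4 and at 51.2, 14.7, 17.2 and 16.7 FPKM in hyperlipidemic replicates 1 to 4. In contrast, Pparg, which drives fat cell formation, was at 4.56 ± 1.36 and 4.66 ± 2.20. Of 9 chondrocyte members 7 were higher. Of these, 1 passed over all genes and 2 when adjusted over the list alone, Col2a1 and Col10a1 (median 0.91, camera adjusted p = 0.0757). Hyperlipidemic replicate 1 held the highest value of Adipoq, Thrsp and Col2a1, and it also held transcripts of skeletal muscle: Mylpf, picked out after its values were seen, was at 14.2, 3.35, 0 and 1.62 FPKM in hyperlipidemic replicates 1 to 4 and listed at 0 in all normal libraries. Of the 11 skeletal muscle members 10 were higher, none past the threshold over all genes or adjusted over the list alone (median 0.69, camera adjusted p = 0.117). Without hyperlipidemic replicate 1 the median log2 change was 0.37 for the adipocyte, 0.26 for the chondrocyte and 0.092 for the skeletal muscle list. It was 0.88 for the adipocyte list without hyperlipidemic replicate 3, and 1.07 for the skeletal muscle list without hyperlipidemic replicate 3 or 4.

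Calls among these genes moved with single libraries. Adipoq no longer passed without normal replicate 1 or 4 (adjusted p of 0.0686 and 0.0529), nor Col2a1 without any 1 normal library or hyperlipidemic replicate 2 (0.0563 to 0.112). Thrsp passed throughout (0.00673 to 0.0174). The adipocyte list passed without normal replicate 4 (camera adjusted p = 0.0265) or hyperlipidemic replicate 3 (0.00523), and with the other pseudocount (0.0372), the stricter filter (0.0344) or quantile normalization (0.0492). The chondrocyte and skeletal muscle lists passed without hyperlipidemic replicate 3 (0.0172 and 0.00796) or 4 (0.0136 and 0.0124). The chondrocyte list also passed with 3 libraries per group (0.0278). All 3 lists passed under median-of-ratios scaling (0.0280).

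Genes of lipid metabolism outside fat cell markers gave few changes. Of 12 members of the fatty acid and triglyceride synthesis list 9 were higher, and Thrsp alone passed, both over all genes and adjusted over the list alone (median 0.20, camera adjusted p = 0.424). That median was 0.011 without hyperlipidemic replicate 1, 0.069 without normal replicate 4 and 0.074 without normal replicate 1. Acly, which makes the precursor of fatty acids, was at 18.6 ± 3.66 and 22.2 ± 1.91 FPKM. Of 14 members of the fatty acid oxidation list 11 were higher, none past the threshold over all genes or adjusted over the list alone (median 0.46, camera adjusted p = 0.0918; 0.0397 without normal replicate 1; median 0.13 without normal replicate 4). Cpt1a, which admits fatty acids to mitochondria, was at 2.87 ± 2.09 and 6.83 ± 0.794 FPKM (log2 change 1.17, adjusted p = 0.250), and Pdk4 at 1.00 ± 0.680 and 1.36 ± 0.497 (0.27, and -0.012 under quantile normalization). The cholesterol synthesis and uptake list passed as lower by camera, with 13 of 21 members lower and none past the threshold over all genes or adjusted over the list alone (median -0.21, camera adjusted p = 0.0261; adjusted p = 0.584 with an estimated correlation). Among its members, the squalene synthase Fdft1 was at 7.12 ± 1.26 and 4.23 ± 0.751 FPKM and the regulator Srebf2 at 19.5 ± 5.26 and 13.0 ± 1.43. The cholesterol list's call ended without normal replicate 2 (0.102, median -0.099), normal replicate 3 (0.155) or hyperlipidemic replicate 4 (0.0552). The cholesterol efflux list (13 members, 7 lower, median -0.14) did not pass (camera adjusted p = 0.209), with no member past the threshold over all genes or adjusted over the list alone. Its median turned to 0.063 without normal replicate 1, and was -0.086 without normal replicate 2 and -0.24 without normal replicate 4.

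Lists of marrow cells differed in direction by camera, red cell and platelet lists passing as higher and lymphoid and granulocyte lists as lower, although none passed with an estimated correlation and no member passed over all genes. Tal1, which is in none of these lists, a transcription factor of blood and red cell formation (chromosome 5, 133864798 to 133878830), rose from 12.8 ± 5.82 to 41.2 ± 8.85 FPKM (3.23-fold between means; log2 change 1.69, adjusted p = 0.0263), a call that ended without normal replicate 1, 3 or 4 or hyperlipidemic replicate 1, 3 or 4 (adjusted p from 0.0521 to 0.117). Of 16 erythroid members 15 were higher. None passed over all genes and 2 rose when adjusted over the list alone, among them the spectrin gene Sptb at 16.5 ± 2.33 and 33.8 ± 8.16 FPKM (list median 0.54, camera adjusted p = 0.00324; adjusted p = 0.584 with an estimated correlation). Of 12 megakaryocyte and platelet members 11 were higher. None passed over all genes and 3, Gp6, Ppbp and Itga2b, rose when adjusted over the list alone (median 1.10, camera adjusted p = 0.00660; adjusted p = 0.573 with an estimated correlation). Itga2b, a platelet integrin, was at 8.35 ± 4.89 and 20.8 ± 5.54 FPKM. The cell cycle list had 17 of 22 members higher, none past the threshold over all genes or adjusted over the list alone (median 0.40, camera adjusted p = 0.0261; adjusted p = 0.584 with an estimated correlation). Its member Kif11 was at 14.1 ± 5.08 and 24.7 ± 6.04 FPKM. The erythroid call ended without normal replicate 2 (0.128) and the megakaryocyte call without normal replicate 3 (0.0645). The megakaryocyte call also ended among genes above 0 in all 8 libraries (0.0939, median 0.67), which leave out Pf4. The cell cycle call ended without normal replicate 2 (0.196), hyperlipidemic replicate 3 (0.112) or hyperlipidemic replicate 4 (0.0667), and under median-of-ratios scaling (0.104).

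Of 16 B cell members 12 were lower. None passed over all genes and 3, Blnk, Igll1 and Ebf1, fell when adjusted over the list alone (median -0.52, camera adjusted p = 0.000632; adjusted p = 0.584 with an estimated correlation). Ebf1, a B lineage transcription factor, was at 16.6 ± 1.55 and 8.64 ± 3.75 FPKM, and the signalling adaptor Blnk at 16.4 ± 3.56 and 7.52 ± 2.47. Of 12 T and NK cell members 10 were lower. None passed over all genes and 2, Cd3g and Lck, fell when adjusted over the list alone (median -0.26, camera adjusted p = 0.00660; adjusted p = 0.546 with an estimated correlation). Lck, a kinase of T cell receptor signalling, was at 5.93 ± 2.55 and 1.79 ± 0.533 FPKM. The B cell median was -0.31 without hyperlipidemic replicate 1, and the T and NK cell median -0.53 without normal replicate 4, -0.42 without hyperlipidemic replicate 1 and -0.16 without hyperlipidemic replicate 3. Of 18 neutrophil and granulocyte precursor members 14 were lower, none past the threshold over all genes or adjusted over the list alone (median -0.18, camera adjusted p = 0.00660; adjusted p = 0.584 with an estimated correlation). Lcn2 was at 716 ± 429 and 365 ± 19.5 FPKM, and the neutrophil call ended under quantile normalization (0.522). The neutrophil median was -0.090 without normal replicate 2 and -0.31 without normal replicate 3. In the macrophage list 7 of 13 members were lower (median -0.02, camera adjusted p = 0.397), in the plasma cell list 6 of 9 were higher (median 0.21, 0.620), and in the mast cell and basophil list 5 of 8 were higher (median 0.21 but mean -0.07 and camera direction down, fry direction up, 0.543). In these lists no member passed over all genes or adjusted over the list alone. On leaving out each library the median ran from -0.15 to 0.056 for the macrophage, 0.12 to 0.40 for the plasma cell and 0.080 to 0.38 for the mast cell and basophil list.

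Genes of inflammation and oxidative stress moved singly, and neither list passed in a shared direction. Il1b, the cytokine interleukin-1 beta, was listed at 0 in normal replicates 1, 3 and 4 and at 1.43 FPKM in normal replicate 2, against 4.53, 6.56, 6.72 and 3.23 FPKM in hyperlipidemic replicates 1 to 4 (adjusted p = 0.0157). Ccl5, a chemokine that attracts T cells, was at 24.6, 11.5, 7.22 and 19.7 FPKM in normal replicates 1 to 4 and at 3.25, 1.60, 0 and 0.441 FPKM in hyperlipidemic replicates 1 to 4 (adjusted p = 0.0159). Of 16 members of the inflammatory cytokine list these 2 passed, over all genes and adjusted over the list alone, in opposite directions (median 0.04, -0.11 under median-of-ratios scaling and -0.047 under quantile normalization; mean 0.15, camera direction down, fry direction up, adjusted p = 0.947; median from 0.023 to 0.20 on leaving out each library). RT1-Ba, a chain of the class II antigen-presenting molecule (chromosome 20, 4066132 to 4070721), fell from 38.3 ± 13.8 to 5.10 ± 2.15 FPKM (7.51-fold between means; log2 change -2.68, adjusted p = 0.00294). Gclc, which makes the precursor of the antioxidant glutathione (chromosome 8, 85059051 to 85097468), rose from 9.69 ± 2.67 to 26.4 ± 6.59 FPKM (2.72-fold between means; log2 change 1.36, adjusted p = 0.0371). It was the only 1 of 19 members of the oxidative stress list to pass over all genes. Adjusted over the list alone Gclc rose and Gpx3 fell, the latter from 157 ± 38.0 to 87.8 ± 6.79 FPKM (list median 0.20, camera adjusted p = 0.353; median 0.051 without normal replicate 4 and 0.13 without hyperlipidemic replicate 4). RT1-Ba passed without each library in turn (adjusted p from 0.00238 to 0.0182). Il1b no longer passed without normal replicate 4 or hyperlipidemic replicate 1, 2 or 3 (0.0511 to 0.0731). Nor did Ccl5 without normal replicate 1 or 4 or hyperlipidemic replicate 3 or 4 (0.0569 to 0.0756), or Gclc without any one library other than normal replicate 2 or hyperlipidemic replicate 2 (0.0708 to 0.153).

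The remaining lists did not pass by camera. Medians of the log2 change were 0.35 for the interferon response (17 of 20 members higher, camera adjusted p = 0.297), 0.24 for oxidative phosphorylation (21 of 25 higher, 0.140) and 0.44 for the immediate early and heat shock genes that respond to handling (11 of 14 higher, 0.165). They were 0.15 for the circadian clock (8 of 13 higher, 0.661), 0.46 for Schwann cells and nerve (6 of 6 higher, 0.401) and -0.09 for smooth muscle and pericytes (5 of 8 lower, 0.140). No member of these 6 lists passed over all genes or adjusted over the list alone. In the glycolysis and hypoxia list 14 of 20 members were higher (median 0.30, 0.323), and in the fibroblast list 4 of 7 were higher (median 0.05 but mean -0.02 and camera direction down, 0.408; median -0.11 under median-of-ratios scaling and -0.011 under quantile normalization). None of either list passed over all genes and 1 each when adjusted over the list alone, Hk2 higher and Thy1 lower, which the naming rule does not cover. In the endothelial list 6 of 12 were higher (median 0.0028, mean 0.04, camera direction down and fry direction up, 0.535; median -0.14 and -0.13 under the same scalings), with no member past either adjustment. On leaving out each library the median ran from 0.042 to 0.29 for the circadian clock, -0.23 to 0.010 for smooth muscle, -0.18 to 0.19 for fibroblasts and -0.099 to 0.15 for endothelial cells. The Schwann cell median was 0.21 without hyperlipidemic replicate 1 and 0.26 without hyperlipidemic replicate 4, the glycolysis median 0.16 without normal replicate 1 and the oxidative phosphorylation median 0.16 without normal replicate 4. The interferon median was 0.14 without normal replicate 1 and 0.21 without hyperlipidemic replicate 3. That list passed without normal replicate 4 (0.00930, median 0.62) or hyperlipidemic replicate 1 (0.0369), the smooth muscle list without hyperlipidemic replicate 2 (0.0334) and among genes of at least 1 kb (0.0381), and oxidative phosphorylation under quantile normalization (0.0209).

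**Figure D3:**
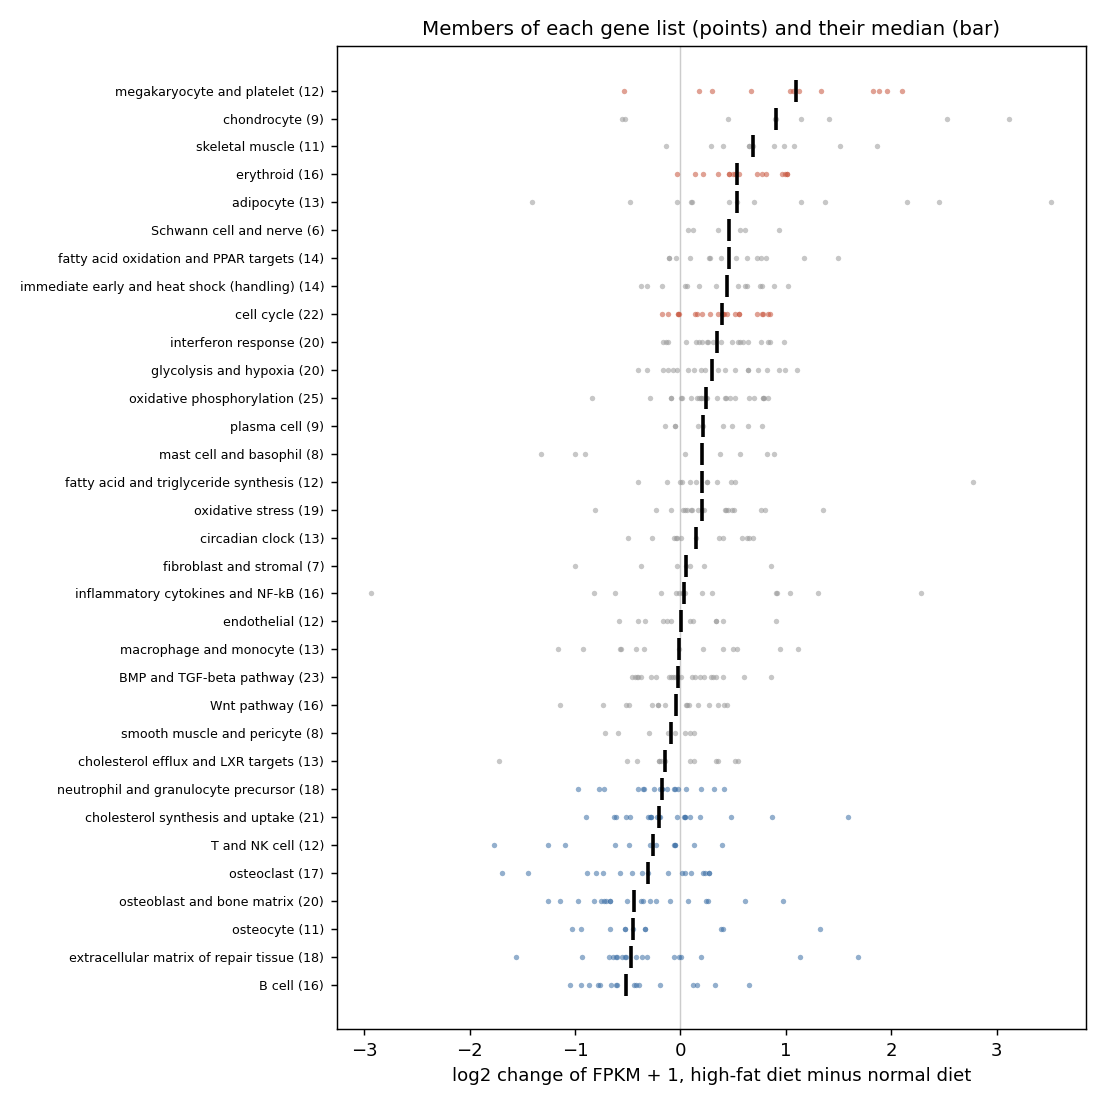
Log2 change of FPKM + 1 (hyperlipidemic minus normal) of each measured member of the 33 gene lists (points) and the list's median (bar), with the number of members in brackets. Lists with a camera adjusted p under 0.05 are coloured, 3 higher in red and 8 lower in blue; none of them passed with an estimated correlation, where the smallest adjusted p was 0.176.

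Over all lists, 11 of 33 passed, 3 higher and 8 lower. None passed with an estimated correlation (smallest adjusted p = 0.176). Nor did any pass with the self-contained test fry for a shared direction (smallest adjusted p = 0.0899, with 7 lists at an unadjusted p under 0.05). In fry's mixed test, where members may move either way, some lists passed. These were the osteoblast (fry mixed adjusted p = 0.00718), inflammatory cytokine (0.00870), fatty acid and triglyceride synthesis (0.00870), osteoclast (0.0393) and oxidative stress (0.0393) lists. The adipocyte, Wnt pathway, megakaryocyte and platelet, and immediate early and heat shock (handling) lists passed too (0.0274 each). Others, such as the B cell (0.0705) and erythroid (0.0816) lists, did not.

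Over all 13742 genes tested, 20 rose and 171 fell in the hyperlipidemic group; at an unadjusted p under 0.05 the counts were 1183 higher and 604 lower. The falls were concentrated in short loci: 158 of the 171 (92.4%) spanned at most 1000 bp, against 13.5% of the loci tested, and 155 of the 171 carry only a clone or provisional name. AABR07031718.1, a locus of 144 bp on chromosome 18, was at 3127, 2967, 1731 and 3844 FPKM in normal replicates 1 to 4 and at 5.15, 4.35, 0 and 10.0 FPKM in hyperlipidemic replicates 1 to 4 (adjusted p = 2.22e-05). One of the loci named 5S_rRNA, a ribosomal RNA of 119 bp on chromosome 19, was at 1854, 426, 32.3 and 375 FPKM in normal replicates 1 to 4 and at 0, 1.497, 0 and 0 in hyperlipidemic replicates 1 to 4 (adjusted p = 0.00178). Among the named genes that fell, the ribosomal protein pseudogenes Rpl26-ps1 (18.3 ± 7.51 to 0.443 ± 0.227 FPKM) and Rpl37-ps1 (10.5 ± 3.71 to 1.08 ± 0.838), the short loci Snrpd2l (8.20 ± 2.39 to 1.05 ± 0.688), Ftl1l1 (21.0 ± 9.87 to 4.55 ± 1.69) and Rps29 (11.4 to 26.1 in the normal libraries and 2.09 to 6.54 in the hyperlipidemic ones), and the mast cell protease gene Mcpt1l1 (78.3 ± 31.8 to 14.7 ± 8.36) were among the 10 largest. This Rps29 locus of 171 bp does not stand for the gene: the Rps29 locus of 1364 bp had a log2 change of -0.031 (adjusted p = 0.967). Of 63 ribosomal protein loci over 1000 bp, 55 were higher and none was called lower (median 0.44, against 0.18 for all genes). Rpl26-ps3 was at 7.98, 4.86, 3.07 and 4.68 FPKM in the normal libraries and listed at 0 in all hyperlipidemic ones. AABR07031718.1 was singled out after its values were seen. The calls of Ftl1l1 and Rps29 ended without any 1 library other than normal replicate 3 (adjusted p from 0.0625 to 0.129 and from 0.0686 to 0.117), and that of Mcpt1l1 without hyperlipidemic replicate 4 (0.0532).

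Of the other named genes that rose, the transcription factor gene Zfp800 went from 2.33 ± 1.33 to 11.4 ± 3.79 FPKM and the actin regulator Fhdc1 from 6.17 ± 2.70 to 20.5 ± 4.55. Mir568 was at 0, 2.69, 0 and 0 FPKM in normal replicates 1 to 4 and at 5.91, 4.40, 10.8 and 8.13 in hyperlipidemic replicates 1 to 4. Its locus spans 96 bp, shorter than the reads of 150 bp, and what FPKM measures at such a length was not tested. Rec114 was at 0, 0.968, 0 and 0 and at 2.70, 2.12, 5.96 and 5.92, and the endothelial proteoglycan gene Esm1 at 0, 2.23, 1.05 and 0 and at 11.3, 4.10, 6.68 and 5.11. Each of these 5 calls ended without hyperlipidemic replicate 1, 3 or 4 or normal replicate 4 (Mir568 0.0563 to 0.129, Rec114 0.0763 to 0.137, Esm1 0.0745 to 0.177, Zfp800 0.0510 to 0.138 and Fhdc1 0.0558 to 0.0971 over all libraries whose leaving out ended the call). They also ended without normal replicate 3, and all but Zfp800 without normal replicate 1. Without hyperlipidemic replicate 2 the calls of Mir568, Esm1 and Zfp800 ended. In the authors' deposited table, 20 genes have a q-value under 0.05, 2 higher and 18 lower, of which 18 are among the 191 called here.

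All 191 genes called had no overlap between the groups, as had 1091 of the genes tested (7.94%, where chance gives 2.86%). The median log2 change of all genes was 0.18, and 0.051 under median-of-ratios scaling and 0.053 under quantile normalization. On leaving out each library it ran from 0.11 to 0.24. The number of calls among longer genes rested on testing them together with short loci: among genes spanning at least 1 kb alone, 1 gene rose, Thrsp, and 2 fell, RT1-Ba and the clone-named AABR07006688.2, each with an adjusted p of 0.0489. There Adipoq, Il1b, Ccl5 and Mcpt1l1 were at an adjusted p of 0.0895, Tal1 at 0.137, Col2a1 at 0.155, and Ctsk and Gclc at 0.175. The number that rose was 47 without normal replicate 2 and 3 without normal replicate 4 or hyperlipidemic replicate 1, 7 without hyperlipidemic replicate 3 and 6 without hyperlipidemic replicate 4. The number that fell was 108, 108 and 103 without hyperlipidemic replicates 1, 3 and 4.

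Among lncRNAs the question was which non-coding transcripts differ around the implant between the diets. Of 14233 tested, 8 rose and 4 fell in the hyperlipidemic group (857 and 192 at an unadjusted p under 0.05). MSTRG.38487.64, an assembled transcript on chromosome 14 (46633725 to 46680767), was listed at 0 in all normal libraries and at 58.4, 68.2, 42.2 and 50.8 FPKM in hyperlipidemic replicates 1 to 4 (adjusted p = 4.89e-06). MSTRG.38487.68, which shares nearly the same interval (46633757 to 46679404), went the other way, at 226, 33.3, 85.3 and 39.0 FPKM in normal replicates 1 to 4 and at 0, 4.07, 0 and 0 in hyperlipidemic replicates 1 to 4 (adjusted p = 0.00118). Another transcript of that locus, MSTRG.38487.96, was at 0, 0, 8.04 and 0.225 FPKM in the normal and at 37.2, 268, 25.1 and 26.6 FPKM in the hyperlipidemic libraries (adjusted p = 0.0174).

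On chromosome 1, MSTRG.855.4 (11903552 to 11915483) was at 6.0e-06, 0, 0 and 0 FPKM in normal replicates 1 to 4 and at 83.7, 49.1, 44.1 and 660.2 in hyperlipidemic replicates 1 to 4 (adjusted p = 4.89e-06). MSTRG.855.14 was listed at 0 in the normal libraries and at 10.4, 1.38, 13.8 and 21.0 FPKM in the hyperlipidemic ones (adjusted p = 0.0446). MSTRG.854.32, near them at 11971459 to 11973055, rose from 1.02 ± 0.999 to 233 ± 220 FPKM (adjusted p = 0.000176). MSTRG.126603.1, which overlaps Exog on chromosome 8, was at 76.7, 8.85, 9.05 and 36.3 FPKM in normal replicates 1 to 4 and listed at 0 in all hyperlipidemic ones (adjusted p = 0.00102). MSTRG.29274.1 was at 35.2, 37.2, 8.51 and 33.9 FPKM in the normal libraries and at 0, 0, 0 and 0.748 in the hyperlipidemic ones (adjusted p = 0.00118). MSTRG.18208.6 was at 0.428, 84.1, 37.6 and 94.7 and at 0, 0, 0.000155 and 0 (adjusted p = 0.0329). MSTRG.38487.64 passed without each library in turn (adjusted p from 0.000159 to 0.00922). MSTRG.855.4 no longer passed without normal replicate 3 or hyperlipidemic replicate 1 (0.0512 to 0.0697), MSTRG.126603.1 without any 1 library other than normal or hyperlipidemic replicate 2 (0.0628 to 0.177), and MSTRG.29274.1 without any other than hyperlipidemic replicate 4 (0.0705 to 0.350). MSTRG.38487.68 no longer passed without any 1 library other than hyperlipidemic replicate 2 (0.207 to 0.721), nor MSTRG.18208.6 without any other than normal replicate 1 (0.349 to 0.721). MSTRG.854.32, MSTRG.38487.96 and MSTRG.855.14 did not pass without any 1 of the 8 libraries (0.0705 to 0.721). All 12 lncRNAs called had no overlap between groups, as had 526 tested (3.70%, where chance gives 2.86%), and the median log2 change was 0.78, or 0.26 under quantile normalization. That median was 0.30 with the other pseudocount, 0.38 with 3 libraries per group, and 0.49 to 1.07 on leaving out each library. The number that rose was 1 to 3 without any one library other than normal replicate 2 (7). The number that fell was 0 without normal replicate 3 or 4 or hyperlipidemic replicate 1 or 3, 1 without normal replicate 2 or hyperlipidemic replicate 4, and 2 without hyperlipidemic replicate 2. In the authors' deposited table, 1 lncRNA has a q-value under 0.05, and it is among those called here.

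The circRNAs, closed loops of back-spliced RNA, were listed in larger numbers in the hyperlipidemic libraries: 107, 521, 184 and 120 were above 0 in normal replicates 1 to 4 and 724, 739, 424 and 569 in hyperlipidemic replicates 1 to 4 (exact permutation p = 0.0571, adjusted 0.143). Of 568 tested, 14 rose and 0 fell (limma; 93 and 1 at an unadjusted p under 0.05). All 14 were listed at 0 in every normal library. The largest were circRNA_5741_Mcpt8l3, at 1.79, 1.37, 1.56 and 1.65 FPKM in hyperlipidemic replicates 1 to 4, and circRNA_10977_Ybx3, at 1.29, 0.749, 1.47 and 1.40. They were followed by circRNA_2791_Usp32 (1.21, 0.667, 1.61 and 1.36), circRNA_4889_Wdr26 (1.13, 0.863, 1.17 and 1.40) and circRNA_5197_Dmp1 (0.483, 0.563, 1.97 and 1.13), the last from a gene of osteocytes. Each of these 5 had an adjusted p of 0.0258. Their host genes did not pass: the log2 change was 0.24 for Mcpt8l3, 0.66 for Ybx3, 0.67 for Usp32, 0.72 for Wdr26 and -0.34 for Dmp1. No circRNA passed with a pseudocount of 1, under quantile normalization, or without normal replicate 1 or 4 or hyperlipidemic replicate 1 or 4, and 1 rose without normal replicate 3 and 81 without normal replicate 2. The median log2 change was 1.15, or -0.017 under quantile normalization, and 53 of the circRNAs tested had no overlap (9.33%, where chance gives 2.86%). A circRNA at 0 in every normal library entered the test only through the hyperlipidemic group. This share and the 14 calls are therefore not separate from the larger numbers listed in that group. In the authors' deposited table, 1 circRNA has a q-value under 0.05, and it is among those called here.

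The series title names co-expression networks, and the last comparison asks whether non-coding RNAs vary together with the genes beside them from library to library, with the group means removed. Over 37574 pairs of a lncRNA and a gene within 100 kb, the median Pearson's r of the residuals across the 8 libraries was 0.117. Pairing the same lncRNAs with genes on other chromosomes 1000 times gave a mean of 0.0865 and a range of 0.0768 to 0.0956 (permutation test, two-sided, p = 0.001, the smallest these re-pairings can give). The pairs hold 12476 lncRNAs and share genes, but the re-pairings drew a gene for each pair separately. This can make the range too narrow, and the p treats dependent pairs as independent. Over 474 circRNAs and their host genes (251 genes) the median r was 0.143, against a mean of 0.0650 and a range of -0.0025 to 0.132 over the re-pairings (permutation test, two-sided, p = 0.001, again the smallest possible). No single pair was tested, since 8 libraries with the group means removed leave few independent values for 1 pair.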

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

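Of the tests below, the 4 counts over other splits, the test of short structured RNAs and that of genes of low level were chosen before their results were seen, and all others after. For the 2 carry-over tests, the member count was added after the median without the library had been seen, and its comparison over choices of 3 libraries after both. All are given.

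A single library lay far from the other 3 of its group in 29 of 268 groups of values, where chance gives about 1 in 20, or 13.4. In 12 of the 29 the 3 other values are all 0, where any remaining value stands apart and the chance value does not apply, which leaves 17. In normal replicate 2 these were Adipoq at 0.0994, Cidec at 0.0489, Plin1 at 0.0727, Thrsp at 0.0172, Il1b at 1.43, Mir568 at 2.69 and Rec114 at 0.968 FPKM, all 0 in the other 3, and Fhdc1 at 10.2. In normal replicate 1 they were Dcn at 96.3, Sparc at 1123, Prg3 at 49.98 and MSTRG.855.4 at 6.0e-06 FPKM, and the 31 genes at 0 there that exceed 10 FPKM in the 7 other libraries. Normal replicate 3 stood apart with Cd74 at 73.5, Sptb at 19.99 and MSTRG.29274.1 at 8.51 FPKM. Hyperlipidemic replicate 1 stood apart with Cidec at 5.54, Plin1 at 13.04, Lpl at 51.2 and Thrsp at 13.8 FPKM. In hyperlipidemic replicate 2 they were Alpl at 23.7, Sparc at 525, Rps15a at 105.6, 5S_rRNA at 1.497, MSTRG.38487.68 at 4.07 and MSTRG.38487.96 at 268 FPKM. Hyperlipidemic replicate 3 stood apart with Cpt1a at 5.66 and MSTRG.18208.6 at 0.000155 FPKM, and hyperlipidemic replicate 4 with MSTRG.29274.1 at 0.748 FPKM.

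Among the 35 splits of the 8 libraries into equal groups, 1 gave as many called genes as the real 191, the real split itself, and the highest other gave 0. For lncRNAs it was again 1, with 12 in the real split and at most 5 in another. For both kinds 1 in 35 is the smallest share these splits can give, unadjusted over the counts tested this way. Chance is therefore made less likely but not excluded. For circRNAs 3 splits reached the real 14, the highest with 164, so chance is not excluded. That split set normal replicates 1, 3 and 4 with hyperlipidemic replicate 3 against the rest, the libraries with the fewest circRNAs, which points to a structure of the samples. For gene lists 2 splits reached the real 11, the other with 11, so chance is not excluded.

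Short loci were lower in the hyperlipidemic libraries. Loss of short RNA in the hyperlipidemic libraries stays open: of the 84 short loci of at least 100 FPKM, 28.6% had a log2 change above 0, but the median was -1.53 (quartiles -3.95 and 0.14), with 32 called lower and 1 higher. More short RNA kept in the normal libraries stays undecided, since the median of -0.66 for structured RNAs rests on 3 loci. Placement of reads from protein genes on pseudogene copies in the normal libraries stays undecided: the copy had the lower log2 change in 27 of 28 pairs (median -0.25 for copies and 0.55 for parents), but loci of up to 300 bp, and longer ones of up to 1000 bp, had a median of -0.24 each. An effect of the diet and a batch that follows the groups stay open as untested.

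For the adipocyte and cartilage transcripts, tissue carried over in hyperlipidemic replicate 1 stays open. In 4 of 13 adipocyte and 3 of 9 chondrocyte members the 3 other hyperlipidemic libraries lay above all normal ones, but in 8 and 9 of the 35 choices of 3 of these 7 libraries some list reached as extreme a count. Without that library the adipocyte median was 0.37 against 0.53, but the chondrocyte median 0.26 against 0.91, so carry-over may account for much of the size of the chondrocyte change. Genes of low level missed in the normal libraries, and the diet as untested, stay open. More of the 19 members of low level had a log2 change above 1 than other genes of that level (Fisher's exact test, one-sided, p = 5.61e-06), but both lists were taken up because they were higher, so this decides nothing.

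For the lower bone cell lists and the higher red cell list, less bone and more marrow in the sampled piece stays open. The erythroid minus the B cell list mean was higher in 4 of 4 hyperlipidemic libraries (exact permutation test, two-sided, p = 0.0286, the smallest possible), as was erythroid minus T and NK cell (0.0286), although all are marrow cells. Relative to the neutrophil and the macrophage list it overlapped (0.0571 each), and adjusted over these 4 none passed (0.0571). The erythroid list had already passed as higher, and the B cell and T and NK cell lists as lower, so contrasts between them restate those calls. Scaling of the deposited values is argued against by the osteoblast median of -0.51 under quantile normalization, against -0.44. The diet, and a batch that follows the groups, stay open as untested.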

How the results depend on the processing

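The settings with 3 libraries per group, genes above 0 in all 8 libraries, genes of at least 1 kb, quantile normalization for lists, pairs without overlap and the mean per host gene were chosen after the data were seen. Over 1872 comparisons for 121 named genes, lncRNAs and circRNAs, 1521 kept direction and side of the threshold, 312 lost and 11 gained a call, and 28 turned direction, none of them called. Over 591 for the 33 lists the numbers were 532, 38, 21 and 0. Except where fewer genes or libraries enter by construction, the cause was not tested.

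Against 20 genes higher and 171 lower, no filter gave 8 and 99, quantile normalization 35 higher, array quality weights 35 higher, and the replicate block 4 higher. There were 7 higher with 3 libraries per group, 11 and 105 with genes above 0 in all 8 libraries, and 1 and 2 with a span of at least 1 kb. Leaving out each library gave 3 to 47 genes higher in hyperlipidemic libraries and 103 to 200 genes lower in hyperlipidemic libraries. Against 8 lncRNAs higher and 4 lower, no filter gave 3 higher, median-of-ratios scaling 5 higher, quantile normalization 14 higher, no trend in the prior variance 2 and 1, array quality weights 20 and 18, and 3 libraries per group 1 higher. Leaving out each library gave 1 to 7 higher and 0 to 3 lower. Against 14 circRNAs higher and 0 lower, there were 0 higher with the other pseudocount, the stricter filter, quantile normalization, the replicate block or 3 libraries per group. No filter gave 218 and 3, array quality weights 357 and 2, and leaving out each library 0 to 81 higher. Against 11 lists passing, the number was 0 with an estimated correlation or with fry for a shared direction. It was 8 to 13, not always the same lists, on leaving out each library.

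Genes that turned direction, none called, did so under median-of-ratios scaling (Ibsp -0.10) and quantile normalization (Tnfrsf11b -0.060, Pdk4 -0.012, RT1-DOb -0.0063). Others turned under array quality weights (Ibsp -0.097, Pparg 0.15, RT1-DOb -0.018), the other pseudocount (Ciita 0.012) and 3 libraries per group (Runx2 0.11, Ibsp -0.34, RT1-DOb -0.28, Ciita 0.0022). On leaving out each library, the log2 change ran from -0.53 to 0.45 for Ibsp, -0.23 to 0.20 for Pparg, -0.56 to 0.22 for Runx2, -0.59 to 0.23 for Alpl, -0.059 to 0.43 for RT1-DOb, -0.27 to 0.13 for Ciita and -0.41 to 0.13 for RT1-DMa.

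Both co-expression results passed under every alternative run. The median r for lncRNAs and genes, with the mean after re-pairing in brackets, was 0.154 (0.0877) at 10 kb, 0.1001 (0.0863) at 1 Mb, 0.103 (0.0743) by Spearman's rho, 0.141 (0.105) with group means kept and 0.106 (0.0855) without overlap, and 0.0883 to 0.145 on leaving out each library. For circRNAs and hosts it was 0.168 (0.0849) by Spearman's rho, 0.304 (0.214) with group means kept and 0.145 (0.0501) as a mean per host, and 0.0748 to 0.194 on leaving out each library. Depth is unknown, so no limit set by it can be given.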

Other observations

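The gene sets in this part were chosen after the values were seen. Among eosinophil genes, Epx rose from 131 ± 24.98 to 250.2 ± 11.7 FPKM (mean ± SD, n = 4 per group; log2 change 0.95, limma adjusted p = 0.0485), a call that ended without normal replicate 3 or 4 or any 1 hyperlipidemic library (0.0745 to 0.179) and under median-of-ratios scaling (0.0904). Prg2 (766 ± 119 and 1274 ± 77.7 FPKM), Prg3 (111 ± 41.3 and 198 ± 41.0) and Ear1 (41.8 ± 10.4 and 84.8 ± 13.0) were higher in all 4 hyperlipidemic libraries without passing, although Prg2 passed under quantile normalization (0.0482), and Ccr3 and Il5ra overlapped.

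Among genes of the class II antigen-presenting molecule, RT1-Ba, RT1-Bb (12.2 ± 4.17 to 3.58 ± 1.11 FPKM) and RT1-Db1 (9.37 ± 1.60 to 2.77 ± 0.287) fell. RT1-Bb no longer passed without any 1 library except normal replicate 3 (0.0705 to 0.140), nor did RT1-Bb (0.175) and RT1-Db1 (0.0895) among genes of at least 1 kb or with a replicate block (0.0675 and 0.0678). The B cell list was also lower by camera (adjusted p = 0.000632), but not with an estimated correlation (0.584) or fry (0.318). RT1-Da, Cd74, RT1-DMa, RT1-DMb, RT1-DOb and Ciita did not pass. RT1-DOb, at a log2 change of 0.16, was at -0.0063 under quantile normalization.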
